A study of Homo sapiens with 24 samples.

How the data were processed

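RNA from A549 cells in control or CAF conditioned medium was measured at 3, 6, 12, 24, 48 and 72 h in 12 mRNA and 12 small RNA libraries, 1 per assay, medium and time. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, polyadenylated RNA was selected on oligo(dT) beads for directional libraries, and small RNA was selected by size on a gel. Medium and time were taken from the labels of each sample, and the value columns were matched to samples through the column code in the sample description. No value column was without a sample.

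The mRNA values are RPKM (reads per kilobase of gene model, scaled to the mapped reads of the library), deposited by the authors to 2 decimals with the length of each gene model. Per the submitters' processing notes, TopHat2, edgeR and the genome build hg19 were used, with no versions given. The counting step, its use of strand, the gene annotation and the joining of the 2 biological replicates of the design text are not given in the sources used here. Reads of a gene and its antisense or overlapping partner, and reads shared by near-identical copies, therefore cannot be told apart, which matters most for gene models under 400 bases. The small RNA values are named TPM per the labels, but each library sums to the same total with no correction for length, so they are RPM, the reads assigned to each miRNA scaled to a common total, as deposited by the authors. Bowtie and hg19 are named for them per the submitters' processing notes, and the miRNA annotation release and the program that predicted further miRNAs are not given in the sources used here. The small RNA table held 2303 named and 279 predicted miRNAs of 18 to 25 bases, of which 63 had 18 bases, and predicted miRNAs took 22.9 to 49.1% of the reads. Names such as chr12_5497 are those of the predicted miRNAs in the authors' table. No reference genome of the authors' build was used here, so genes are given with the chromosome of the authors' table and without coordinates.

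Depth was worked out from the smallest steps between values. In the small RNA libraries 100% of the 858 to 1232 low values checked per library were whole multiples of 1 read within 0.1 read, which gave 0.868 to 5.77 M reads per library. In the mRNA libraries 100% of the 69 to 119 values checked per library, from gene models under 400 bases, were whole within 0.1 read, which gave 23.9 to 40.6 M reads. RPKM times gene length summed to 96.6 to 97.7% of these reads. Intervals from recovered reads cover counting error only.

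Tests were run in R 4.3.3 with limma 3.58.1. RPKM were tested as log2(RPKM + 0.5) in genes with a mean of at least 1 RPKM, and miRNAs as log2(RPM + 1) with a mean of at least 10. A fold change on these scales understates the change of low genes. The effect over the 6 times was fitted with time as a factor and 5 residual degrees of freedom. The early (3, 6 and 12 h) and late (24, 48 and 72 h) effects and their difference were fitted together, with 3 pairs each and 4 residual degrees of freedom. Change with time was fitted as a slope on log2 of the hours with medium as a term and 9 residual degrees of freedom. That fit counts the control and CAF medium libraries of a time as separate replicates, although there are only 6 times. Scatter shared by the libraries of a time is therefore counted more than once, and the p-values for change with time can be too small. Moderated two-sided tests (lmFit and eBayes with a mean-variance trend) were adjusted by Benjamini-Hochberg over all tested genes or miRNAs at 0.05. Single times had no test and were described by a log2 difference of at least 1.

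Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists with at least 5 tested members, and again with an estimated correlation and with fry. There were 22 lists, and 3 more set by name or chromosome (ribosomal proteins, mitochondrial chromosome and replication-dependent histones). The 15 miRNA families had no set test. In 200 random lists of 18 genes, camera gave an unadjusted p under 0.05 for 3.5, 1.5, 3.5, 2 and 2% in the fits over the 6 times, over 3 to 12 h and over 24 to 72 h, of their difference and of time. Genes drawn at random need not share the correlation of co-regulated lists. Over the 6 times it was estimated at 0.945 for mitosis, 0.671 for NF-kB and 0.617 for DNA replication. These shares therefore do not show the error rate of camera for such lists. fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called the BMP and ID list overall (adjusted p = 0.00674), NF-kB early (0.0404), and mitosis (0.0289), DNA replication (0.0289) and BMP and ID (0.0448) late. It called none in the difference (fry, smallest adjusted p = 0.0534), and for change with time it called 6 lists.

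The lists, the thresholds, the tests and the rule for named genes were fixed before the data were examined. The rule took, for the effect over the 6 times, the 12 largest rises and 12 largest falls among genes past the threshold with the same direction at 6 of 6 times. For the early, late, difference and time fits it took the 5 largest in each direction past the threshold. For each single time it took the 2 largest in each direction with a mean of at least 5 RPKM, and in each list up to 4 members with the smallest p. The genes it always took include CDH1, EPCAM, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2, TWIST1, MMP2, ACTA2, IL6 and IL8. For miRNAs it took the 5 with the smallest p in each direction where none passed over the 6 times and 4 in other fits, 2 per single time with a mean of at least 50 RPM, the 5 most abundant and the miR-200 family. COL1A2 and COL3A1 are named outside the rule and were chosen after their values were seen.

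The limma steps were tested on simulated data for the 12029 genes with 200 changed. Of genes changed by log2 0.5, 1 and 2, the overall fit found 71.6, 100 and 100%, the early fit 13.4, 94 and 100%, the late fit 11.9, 89.6 and 100%, and the difference 2.99, 50.7 and 97%. For the time fit a size was the change over 2 units of log2 time, and 100% of each size was found. Its simulated genes had a flat baseline and only the residual noise of the fit with time as a factor. They lacked real scatter between times, so these 100% can overstate the power of that fit. In these simulations 7.65, 7.38, 4.29, 9.09 and 3.38% of the calls were unchanged genes. The miRNA step was tested on 470 miRNAs with 40 changed, and its overall fit found 14.3, 69.2 and 92.3% of the 3 sizes. edgeR 4.0.16 (quasi-likelihood test) was run on the recovered small RNA reads as an alternative. The other alternatives were the pseudocount, the filter on low values, median centring, quantile normalization, no mean-variance trend, no time term, a log2 time term in place of time as a factor, controls alone for change with time, rescaling without the 3 most abundant miRNAs, and leaving out each time in turn. Libraries of medium and time cannot be split further by a batch, since the labels name none.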

Results

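A549 cells, an established human lung adenocarcinoma line of epithelial origin, were kept in control medium or in medium conditioned by cells that the labels call CAF. In this field CAF usually stands for cancer-associated fibroblast, although the labels do not spell it out. Cells were collected at 6 times, 3, 6, 12, 24, 48 and 72 h, and polyadenylated RNA and small RNA were sequenced. Each of the 2 assays has 6 control and 6 CAF medium libraries, 1 per medium and time. The design text speaks of 2 biological replicates per sample, which are not separate in the values used here, so a single time has no replicate check. The 6 times were therefore taken as the replicates of the medium effect, each CAF medium library against the control of its own time. Beyond that design text nothing says that the libraries came from separate cultures, so the p-values rest only on the spread between these libraries, which may be technical. In the fit over the 6 times that spread also holds any real change of the medium effect with time. A response present at only some times can therefore miss the threshold.

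The mRNA values imply 23.9 to 29.3 M reads per library at 3 to 12 h and 33.9 to 40.6 M at 24 to 72 h. The small RNA libraries held 0.868 to 5.77 M reads assigned to miRNAs. The 10 most abundant genes took 13.3 to 19.5% of the summed RPKM, and the 10 most abundant miRNAs took 75.1 to 84.5% of the miRNA reads. Of 22026 genes 12029 were tested, and of 2582 miRNAs 470. The series title concerns markers of epithelial-mesenchymal transition, the process in which epithelial cells lose their junctions and take on a migratory, fibroblast-like state.

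The first question was which genes CAF medium changed across the 6 times. TXNIP (chromosome 1), which encodes the thioredoxin-interacting protein, had the largest rise. Its mean was 4.94 ± 8.60 RPKM in control medium and 19.8 ± 23.4 in CAF medium (SD over 6 times), a log2 change of 2.39 ± 0.25 (SE, adjusted p = 0.00548), and it was higher at 6 of 6 times. TNNI3 (chromosome 19), the cardiac form of troponin I, rose from 2.09 ± 2.74 to 7.60 ± 7.38 RPKM (log2 1.73 ± 0.20, adjusted p = 0.00749). HES7 (chromosome 17), a transcriptional repressor of the Notch pathway, rose from 2.94 ± 2.98 to 7.63 ± 2.33 RPKM (log2 1.60 ± 0.31, adjusted p = 0.019). The gasdermin gene GSDMB and the class II histone deacetylase gene HDAC5, both on chromosome 17, rose by log2 1.45 ± 0.15 and 1.33 ± 0.19 (adjusted p = 0.00548 and 0.0117).

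Among the genes that fell, CCL2 (chromosome 17), a chemokine that attracts monocytes, went from 29.7 ± 27.8 to 7.72 ± 2.28 RPKM (log2 -1.57 ± 0.34, adjusted p = 0.0226). RRM2 (chromosome 2), the small subunit of ribonucleotide reductase, went from 41.8 ± 24.5 to 20.9 ± 15.2 RPKM (log2 -1.12 ± 0.18, adjusted p = 0.0133). ODC1, which makes polyamines from ornithine, went from 64.3 to 31.8 RPKM (log2 -1.10 ± 0.15, adjusted p = 0.0106). The replication genes MCM10, UHRF1 and CCNE2 had log2 changes of -1.13, -0.99 and -0.99, the transcription factor gene ATF5 of -0.95 and the chemokine gene CXCL2 of -0.94. The other large rises were those of the long non-coding RNA LINC00263 (log2 1.42, from 6.17 to 17.0 RPKM), BC038541 (1.42), FCHO1 (1.40), FXYD7 (1.35), CALY (1.35), PALM3 (1.34) and BC015429 (1.33), with FXYD7, CALY and PALM3 below a mean of 1 RPKM in control medium. The other large falls were those of SAMD15 (log2 -1.50), LPAL2 (-0.96), MIR548I4 (-1.96) and DQ582201 (-1.34). MIR548I4 and DQ582201 are gene models shorter than 400 bases, the latter on the mitochondrial chromosome, and their reads cannot be told apart from those of repeated copies. Each of these 24 genes moved in 1 direction at 6 of 6 times.

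By limma with Benjamini-Hochberg adjustment over the 12029 genes, 729 genes rose and 497 fell, of which 580 and 399 moved the same way at 6 of 6 times. Only 44 of those that rose and 9 of those that fell reached a 2-fold change. The count was 34 without the 6 h pair, 35 without the 12 h pair, 117 without the 24 h pair and 729 without the 48 h pair. HES7, CCL2, MCM10 and CCNE2 lost their calls without the 6 h pair (adjusted p = 0.0627, 0.0753, 0.0521 and 0.0743) and without the 12 h pair (0.0689, 0.0766, 0.0669 and 0.0689). Without the 24 h pair HES7, MCM10 and CCNE2 lost theirs again (0.0605, 0.0612 and 0.0697), as did FXYD7 (0.0593), CALY (0.0623), PALM3 (0.0589) and MIR548I4 (0.0535). HDAC5, RRM2, UHRF1, ATF5, CXCL2, BC038541, FXYD7, CALY, PALM3 and MIR548I4 also lost theirs without 6 h (0.0502, 0.0502, 0.0502, 0.0537, 0.0545, 0.0521, 0.0611, 0.0542, 0.0659 and 0.0508) and without 12 h (0.0511, 0.0538, 0.0569, 0.0571, 0.0571, 0.0548, 0.0669, 0.0676, 0.0589 and 0.0571). LINC00263 lost its call without 6 h (0.0502), and ODC1 and DQ582201 lost theirs without 12 h (0.0538 each). TXNIP, TNNI3, GSDMB, FCHO1, BC015429, SAMD15 and LPAL2 stayed past the threshold whichever time was left out. With no time term no gene passed (limma, 0 of 12029, 1691 at an unadjusted p under 0.05), and with no filter on low values none passed either (0 of 22026, 4744 unadjusted).

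The genes that the study's title points to moved in both directions. EPCAM, an epithelial adhesion molecule, rose from 1.32 to 2.75 RPKM (log2 0.82 ± 0.16, adjusted p = 0.0174). CDH1, which encodes E-cadherin of the epithelial adherens junction, measured 10.3 ± 7.15 RPKM in control and 16.0 ± 12.7 in CAF medium (log2 0.54 ± 0.20, adjusted p = 0.104), and passed the test over 24 to 72 h (log2 0.94, adjusted p = 0.0434). SNAI2 (chromosome 8), the transcription factor SLUG that represses E-cadherin, fell from 11.6 ± 4.37 to 6.95 ± 2.55 RPKM (log2 -0.70 ± 0.10, adjusted p = 0.0104). It fell both over 3 to 12 h (log2 -0.56, adjusted p = 0.0333) and over 24 to 72 h (-0.84, adjusted p = 0.00553). ACTA2, smooth muscle actin, rose by log2 0.36 (adjusted p = 0.0442).

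The mesenchymal genes VIM, CDH2 and FN1, which encode vimentin, N-cadherin and fibronectin, had log2 changes of 0.002, -0.22 and 0.07 (adjusted p = 0.99, 0.184 and 0.805), and the sign of VIM is reversed by median centring and quantile normalization. The values for ZEB1, ZEB2, TWIST1 and MMP2 were 0.09, -0.04, 0.38 and 0.53 (adjusted p = 0.587, 0.857, 0.0632 and 0.0612), none past the threshold. SNAI1 measured 0.42 to 1.72 RPKM and was too low to be tested. EPCAM lost its call without the 6 h pair (adjusted p = 0.0611) or the 12 h pair (0.0569), and ACTA2 lost its call whichever time was left out (0.0528, 0.0872, 0.113, 0.155, 0.0501 and 0.0768 without 3, 6, 12, 24, 48 and 72 h). CDH1 passed without the 3 h pair (0.018), TWIST1 without the 72 h pair (0.0226) and MMP2 without the 48 h pair (0.034).

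**Figure D1:**
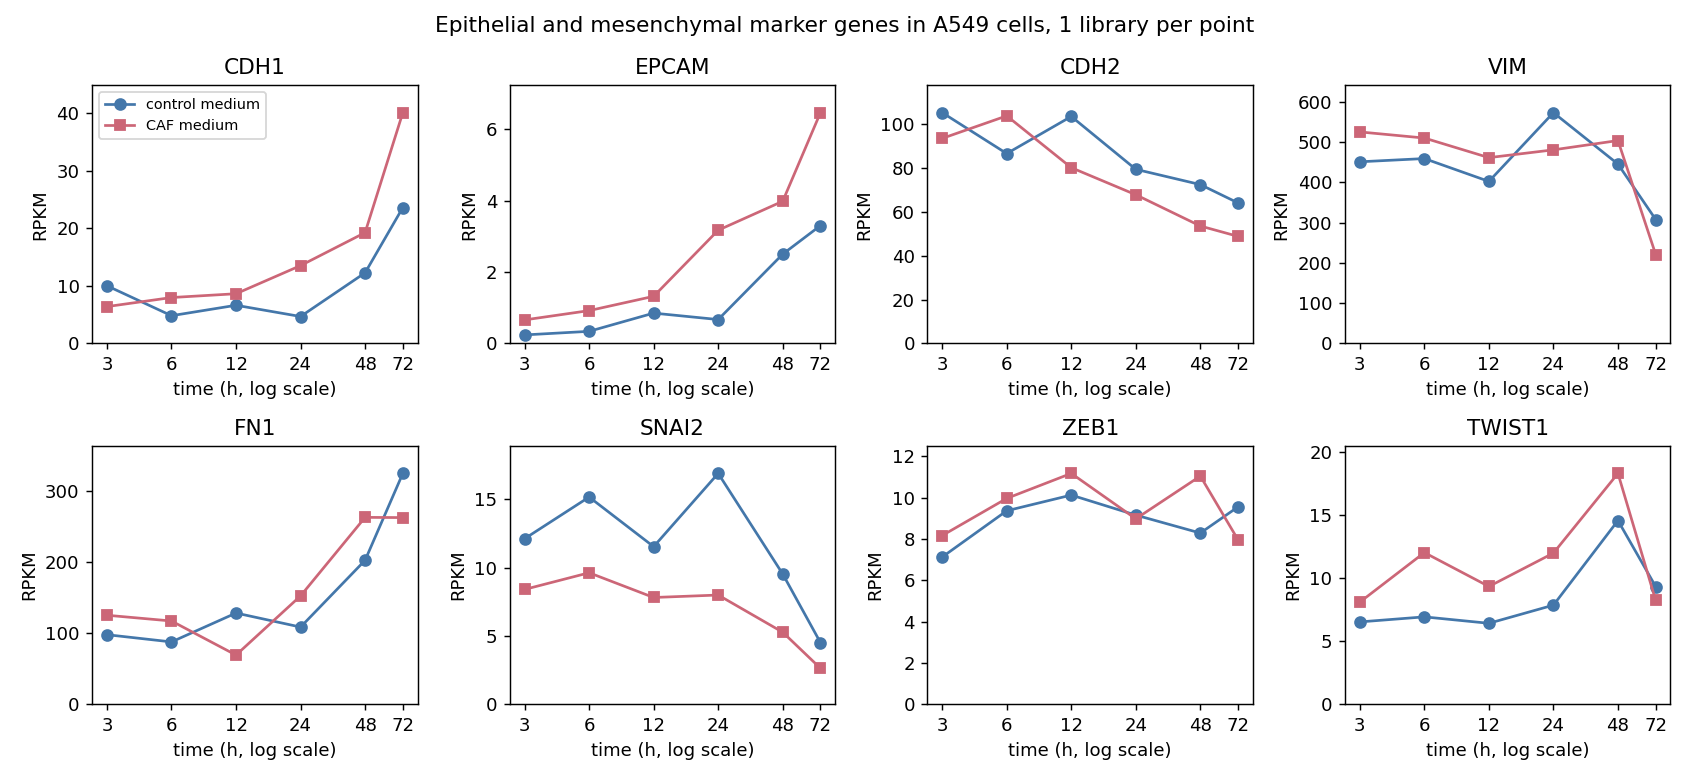
RPKM of epithelial and mesenchymal genes against hours in culture, with 1 point per library in control and in CAF medium. SNAI2 lies lower in CAF medium at 6 of 6 times, and CDH1 and EPCAM lie highest at the late times.

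Gene lists set before the data were examined were tested with camera against all other tested genes. Over the 6 times 11 of the 21 testable lists passed, and none did when the correlation between genes was estimated instead of preset. The DNA replication list had the lowest p: 20 of its 20 members had a negative change (median log2 -0.55), 7 of them past the test over all genes and 16 adjusted over the list alone (adjusted p = 2.61e-08 for the list, adjusted p = 0.582 with an estimated correlation). GINS2, a helicase subunit, fell by 0.63 on the log2 scale beside UHRF1, RRM2 and CCNE2. The mitosis list also fell (median log2 -0.50, adjusted p = 1.16e-05, adjusted p = 0.582 with an estimated correlation), with UBE2C and CCNA2, a ubiquitin-conjugating enzyme and cyclin A2, the 2 of 20 members past the test over all genes, and 2 adjusted over the list alone. Its fall lay at 24 to 72 h, since over 3 to 12 h 15 of the 20 members had a positive change (median log2 0.12, adjusted p = 0.474). In the BMP and ID list 3 of 6 members fell over all genes and 3 adjusted over the list alone (adjusted p = 0.000252, adjusted p = 0.309 with an estimated correlation). They were ID2 (log2 -0.93, adjusted p = 0.00548) and ID3 (-0.72, adjusted p = 0.00749), inhibitors of basic helix-loop-helix factors, and ATOH8 (-0.68, adjusted p = 0.0223).

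The hypoxia and glycolysis list fell (adjusted p = 0.000381, adjusted p = 0.582 with an estimated correlation), with 4 of 19 members past the test over all genes and 6 adjusted over the list alone. These included the glycolytic enzyme genes LDHA (log2 -0.50) and PGK1 (-0.43), the carbonic anhydrase gene CA9 (-0.58) and the glucose transporter gene SLC2A1 (-0.56). The NF-kB and cytokine list fell (adjusted p = 0.00134, adjusted p = 0.582 with an estimated correlation) and lost its call without the 3 h pair (adjusted p = 0.0966). This rests on 3 to 12 h: over 24 to 72 h 12 of its 18 members had a positive change (median log2 0.23, adjusted p = 0.19), with 0 past limma's test over all genes and 5 up and 1 down adjusted over the list alone. Of its 18 members 5 fell over all genes and 6 adjusted over the list alone, among them CXCL3 (log2 -0.74) and CXCL1 (-0.79). In the NRF2 list (adjusted p = 0.0111, adjusted p = 0.582 with an estimated correlation) SRXN1 (log2 -0.53) and OSGIN1 (-0.92) fell while AKR1C1 (0.62) rose. That is 1 up and 2 down of 17 over all genes, and 1 and 3 adjusted over the list alone, and the list missed the threshold without the 48 h pair (adjusted p = 0.051).

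Heat shock genes (adjusted p = 0.0197, adjusted p = 0.538 with an estimated correlation) had 0 of 10 members past limma's test over all genes and 2 adjusted over the list alone, with HSP90AA1 at log2 -0.47 (adjusted p = 0.059) and HSPA8 at -0.52 (adjusted p = 0.0633). Genes of the mitochondrial chromosome (adjusted p = 0.0197, adjusted p = 0.582 with an estimated correlation) had 1 of 15 members down over all genes, DQ582201, and 1 adjusted over the list alone, and this list missed the threshold without the 12 h pair (adjusted p = 0.0637). ER chaperones passed narrowly (adjusted p = 0.0451, adjusted p = 0.582 with an estimated correlation) with 0 of 16 members past the test either way. They missed it without the 3, 6, 12 or 24 h pair (adjusted p = 0.0545, 0.0507, 0.0992 and 0.0679). Upward, the sterol and fatty acid synthesis list rose (adjusted p = 0.00319, adjusted p = 0.582 with an estimated correlation), with 4 of 18 members over all genes and 6 adjusted over the list alone. They included FDFT1 (log2 0.63), MVD (0.47), DHCR7 (0.46) and FASN (0.42), enzymes of cholesterol and fatty acid synthesis. Ribosomal protein genes moved by a median log2 of 0.14 (adjusted p = 0.000381, adjusted p = 0.746 with an estimated correlation), with RPL17 the 1 of 72 members past the test over all genes and 0 adjusted over the list alone. Reads of ribosomal protein genes can be shared with their many pseudogenes.

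Of the lists that did not pass, the epithelial list (adjusted p = 0.769) had 1 of 13 members past the test both over all genes and adjusted over the list alone. The mesenchymal list (adjusted p = 0.866) had 2 of 25 up, WNT5A (log2 0.56) and ACTA2, and 2 down, SNAI2 and THBS1 (-0.78), with 5 up and 2 down adjusted over the list alone. Its median of 0.002 turned negative under median centring (-0.01) and quantile normalization (-0.05). TGF-beta targets (adjusted p = 0.143) had TGFB1 (log2 0.54) up and ITGB6 (-0.74), SMAD7 (-0.40) and SKIL (-0.44) down, with 2 up and 3 down adjusted over the list alone. In the remaining lists the members past the test over all genes were PIM1 (0.94) of the STAT3 list, HERC5 (0.44) and OAS3 (-0.57) of the interferon list, DUSP1 (0.55) of the immediate early list and MMP14 (1.04) of the matrix protease list. They were also CEBPB (0.50), CTH (0.54) and SLC7A11 (-0.74) of the ATF4 list, BBC3 (0.66), RRM2B (0.42), TP53I3 (-0.70) and FAS (-0.56) of the p53 list, and HIST1H2BN (0.53), HIST2H2BE (-0.64), HIST1H2AC (-0.46) and HIST1H4H (-0.77) of the histone list. The adjusted p of these lists were 0.806, 0.857, 0.24, 0.102, 0.449, 0.857 and 0.315, in the order named. Adjusted over the list alone, the counts up and down were 1 and 0, 2 and 1, 1 and 0, 2 and 0, 2 and 2, 2 and 3, and 2 and 4. The interferon list's median of 0.05 turned negative under quantile normalization (-0.03), and its test pointed down.

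The lists of fibroblast genes (3 tested: COL1A1, FAP and FBN1), other non-epithelial cells (1: CD68), alveolar and mucous genes (1: ABCA3) and metallothioneins (3: MT2A, MT1F and MT1X) were too small to test, and none of these members passed over the 6 times. The collagen genes COL1A2 and COL3A1, abundant in fibroblasts, reached at most 0.12 and 0.16 RPKM in any library. Genes of the lists that were not analysed here are CLDN4, CFB, IRF9, IER3, SREBF2, SFTPA1, AGER, SCGB1A1, MT1E, MT1G, MT1H, MT1M, HSPA1A and HSPA1B.

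**Figure D2:**
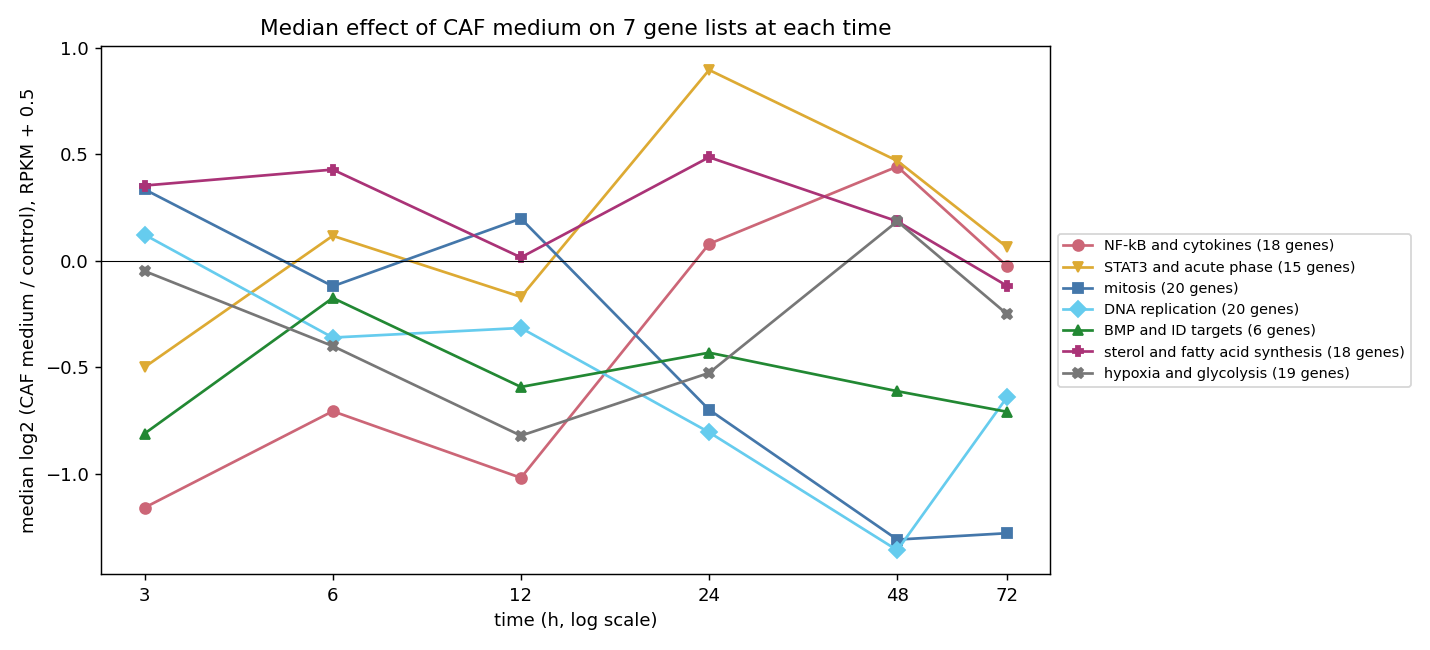
Median log2 difference between CAF and control medium of the tested members of gene lists at each of the 6 times in hours. The NF-kB list is low at 3, 6 and 12 h (-1.16, -0.71 and -1.02), and the mitosis list is low at 24, 48 and 72 h (-0.70, -1.31 and -1.28).

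Over 3 to 12 h CAF medium lowered the transcripts of inflammatory mediators. CCL2 fell by 2.43 ± 0.30 on the log2 scale (adjusted p = 0.00929), from 85.3 to 6.22 RPKM at 3 h. That control stood apart from the others, which had at most 25.2 RPKM, and the log2 differences at 6 and 12 h were smaller (-1.89 and -1.72). IL6, the interleukin 6 gene, fell by 1.60 ± 0.27 (adjusted p = 0.0131). The neutrophil chemokine genes CXCL1, CXCL2 and CXCL3 fell by 1.22, 1.28 and 1.14 (adjusted p = 0.00929, 0.0109 and 0.0109), and CLCF1, a cytokine of the interleukin 6 family, by 1.49 ± 0.21 (adjusted p = 0.0109). IL8, named CXCL8 in newer annotations, was at log2 -0.93 (adjusted p = 0.0507). Of the 18 members of the NF-kB and cytokine list 18 were lower, 10 past the test over all genes and 16 adjusted over the list alone (adjusted p = 1.53e-15, adjusted p = 0.181 with an estimated correlation). HES7 and TXNIP had the largest rises (log2 2.34 ± 0.30 and 2.34 ± 0.35, adjusted p = 0.00929 and 0.0109), followed by the homeobox gene GBX1 (1.87), PALM3 (1.75) and HDAC5 (1.62).

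DQ584698 (57 bases, log2 -2.45) and SNORD104 (80 bases, -1.51) also fell, and as short models they can hold reads of overlapping or repeated transcripts. ADM, which encodes adrenomedullin, fell by 1.22 on the log2 scale (adjusted p = 0.0286) and was the 1 of 19 hypoxia genes past the test over all genes, with 9 adjusted over the list alone. The hypoxia list passed (adjusted p = 1.73e-06, adjusted p = 0.662 with an estimated correlation). In the BMP and ID list ID2 (log2 -0.87) and ID3 (-0.73) fell, 2 of 6 over all genes and 4 adjusted over the list alone (adjusted p = 0.00116, adjusted p = 0.388 with an estimated correlation). The acute phase genes SAA1 and SAA2, near-identical copies whose reads may be split between them, fell by 1.39 and 1.49 (adjusted p = 0.0294 and 0.0264), while PIM1 of the same STAT3 and acute phase list rose by log2 0.98 (adjusted p = 0.0273), and the list did not pass (adjusted p = 0.13). KRT19, an epithelial keratin, rose by log2 1.58 (adjusted p = 0.0217), while the tight junction gene CLDN1 (-0.91) and the mucin gene MUC1 (-0.86) fell. COL1A1 rose by 1.11 (adjusted p = 0.0259), the 1 of 3 fibroblast-list members to pass. Smaller list calls were those of DNA replication (2 of 20 down over all genes, 3 adjusted over the list alone, adjusted p = 0.0151, adjusted p = 0.781 with an estimated correlation) and the mitochondrial chromosome (3 of 15 down both ways, 1 up adjusted over the list alone, adjusted p = 0.0151, adjusted p = 0.662 with an estimated correlation). The sterol list rose with FDFT1 (0.75), the 1 of 18 members past either test (adjusted p = 0.0396, adjusted p = 0.781 with an estimated correlation).

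By limma 453 genes rose and 224 fell over 3 to 12 h, a split of 299 and 230 under quantile normalization. Leaving out the 6 h pair left 5 genes and the 12 h pair 0 (limma, 2187 at an unadjusted p under 0.05), in smaller fits, whereas the NF-kB, hypoxia and BMP lists passed whichever time was left out. DNA replication missed the threshold without 6 h (adjusted p = 0.135) or 12 h (0.0752), the mitochondrial list without 12 h (0.0934), and the sterol list without 3 h (0.143), 6 h (0.194) or 48 h (0.0504). Without the 24 h pair, which enters the shared spread, the count was 1084.

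**Figure D3:**
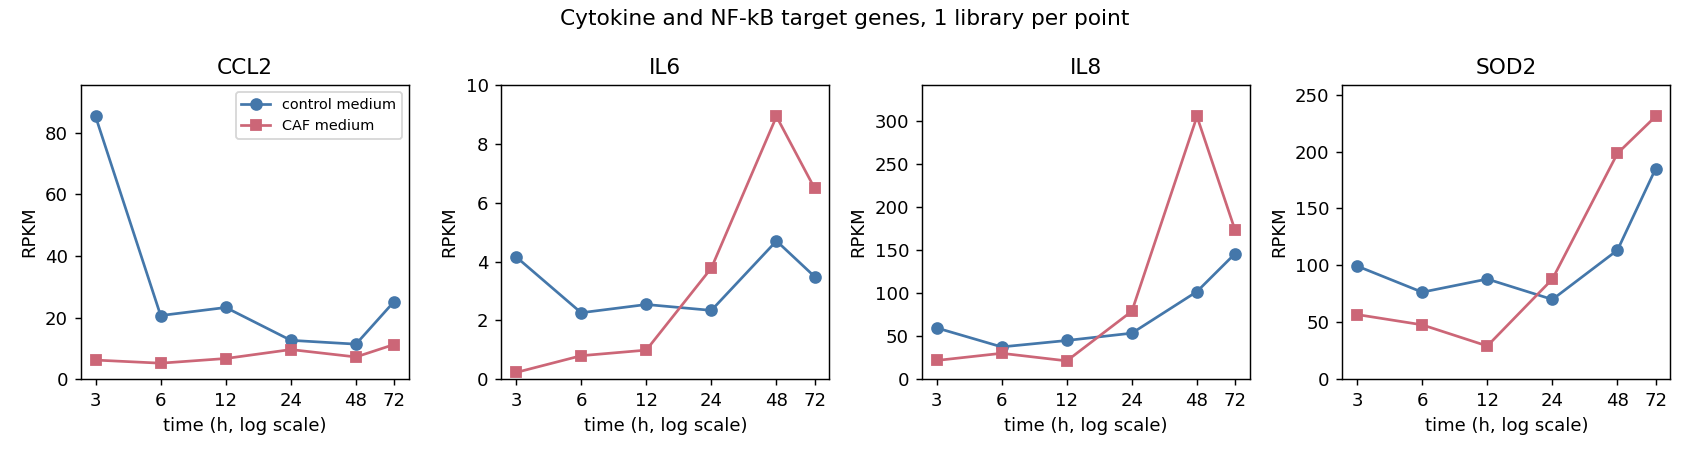
RPKM of cytokine and NF-kB genes against hours in culture, with 1 point per library. CCL2 in CAF medium lies below the control at 6 of 6 times, from 6.22 against 85.3 RPKM at 3 h.

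Over 24 to 72 h the largest group change was in the genes of cell division. Of the 20 mitosis genes 20 fell past the test over all genes and 20 adjusted over the list alone (median log2 -1.09, adjusted p = 1.26e-25, adjusted p = 0.294 with an estimated correlation). Among them the proliferation marker MKI67 fell by 1.23 (adjusted p = 0.00366), CCNA2 by 1.16 and the mitotic kinesin gene KIF20A by 1.18. Of the 20 DNA replication genes 15 fell over all genes and 19 adjusted over the list alone (median log2 -0.90, adjusted p = 1.6e-18, adjusted p = 0.294 with an estimated correlation), with RRM2 at -1.58, CDC45 at -1.43 and CDC6, which loads the replicative helicase, at -1.21. The largest single falls were those of MIR548I4 (-2.82, 61 bases), SAMD15 (-1.78), MCM10 (-1.69 ± 0.20, adjusted p = 0.00331), the cell cycle transcription factor gene MYBL2 (-1.67 ± 0.19, adjusted p = 0.00331) and the transferrin receptor gene TFRC (-1.63 ± 0.31, adjusted p = 0.0142).

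TXNIP rose by log2 2.44 ± 0.35 over 24 to 72 h (adjusted p = 0.00442), TNNI3 by 2.03, CALY by 1.86 and CAPN12, a calpain protease gene, by 1.70. MIR21 rose by 2.27 (adjusted p = 0.0297), but this model of 72 bases lies within a longer transcript and its polyadenylated reads do not measure the mature miRNA. GDF15, a stress-induced cytokine of the TGF-beta superfamily and a p53 target, rose by 1.64 (adjusted p = 0.0288), and the interferon-inducible genes IFITM1 and BST2 rose by 1.17 and 1.13 (adjusted p = 0.013 and 0.0279). Neither list passed: the interferon list had 8 members positive and 8 negative (median log2 -0.03, adjusted p = 0.416), and in the p53 list (adjusted p = 0.416) RRM2B (log2 0.58) also rose while TP53I3 (-0.89) fell. ID2 (-0.99) and ID3 (-0.72) fell again, 2 of 6 in the BMP and ID list over all genes and 3 adjusted over the list alone (adjusted p = 0.00163, adjusted p = 0.294 with an estimated correlation). The matrix protease list rose with MMP14 (1.17), a membrane-bound metalloprotease, 1 of 9 either way (adjusted p = 0.00899, adjusted p = 0.504 with an estimated correlation). The immediate early list rose with DUSP5 (1.21), 1 of 16 either way (adjusted p = 0.00754, adjusted p = 0.699 with an estimated correlation), and the STAT3 list with PIM1 (0.90), 1 of 15 either way (adjusted p = 0.0177, adjusted p = 0.699 with an estimated correlation).

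The ribosomal (0 of 72, adjusted p = 0.000374, adjusted p = 0.724 with an estimated correlation) and sterol lists (0 of 18, adjusted p = 0.00898, adjusted p = 0.7 with an estimated correlation) moved up with no member past limma's test either way. Downward, the NRF2 list (adjusted p = 0.0108, adjusted p = 0.699 with an estimated correlation) had 0 of 17 members past the test over all genes and 1 up and 2 down adjusted over the list alone. Heat shock genes had 0 of 10 either way (adjusted p = 0.0299, adjusted p = 0.504 with an estimated correlation). The histone list fell with HIST1H4H (-1.19), 1 of 11 over all genes and 5 adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.699 with an estimated correlation). Histone messages lack a poly(A) tail, so in these libraries their level also depends on the selection of polyadenylated RNA, and the summed histone RPKM ranged from 49.1 to 116.9. By limma 163 genes rose and 329 fell over 24 to 72 h, with 277 in all without the 24 h pair and 31 without the 48 h pair. The STAT3, sterol, heat shock and histone lists missed the threshold without 24 h (adjusted p = 0.0834, 0.228, 0.202 and 0.103), and the immediate early, NRF2 and matrix protease lists without 48 h (0.367, 0.143 and 0.0807).

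The difference between the late and the early effect was tested directly. IL6, low in CAF medium over 3 to 12 h, moved up by log2 2.35 ± 0.38 in the late effect relative to the early (adjusted p = 0.0364). SOD2, the mitochondrial superoxide dismutase gene and an NF-kB target, and STC2, a secreted glycoprotein gene, moved up by 1.50 each (adjusted p = 0.0385), and PIP and BC016015 by 2.12 and 1.28. In the other direction MYBL2 (-1.75), C2orf48 (-1.75), the mitotic phosphatase gene CDC25C (-1.72), the kinetochore gene SPC25 (-1.60) and KIF20A (-1.53) moved down (adjusted p = 0.0364 each). The NF-kB list shifted up by a median log2 of 1.14, with 2 of 18 members over all genes and 15 adjusted over the list alone (adjusted p = 4.6e-22, adjusted p = 0.0984 with an estimated correlation). The mitosis list shifted down by a median of -1.13, with 9 of 20 over all genes and 20 adjusted over the list alone (adjusted p = 7.52e-28, adjusted p = 0.335 with an estimated correlation). TOP2A (-1.18), AURKB (-1.33) and CENPF (-1.46) were among them.

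DNA replication (median -0.73) had 0 of 20 members past limma's test over all genes and 16 adjusted over the list alone (adjusted p = 3.08e-11, adjusted p = 0.497 with an estimated correlation). The histone list (median -0.39) had 0 of 11 over all genes and 2 down adjusted over the list alone (adjusted p = 0.0371, adjusted p = 0.542 with an estimated correlation). The STAT3 list (median 0.26, adjusted p = 0.000254, adjusted p = 0.542 with an estimated correlation) had 0 of 15 over all genes and 2 up adjusted over the list alone, SAA1 (2.02) and SAA2 (2.04). The hypoxia list (median 0.31, adjusted p = 0.000555, adjusted p = 0.542 with an estimated correlation) had 0 of 19 and, adjusted over the list alone, 1, ADM (1.73). The immediate early list (median 0.36, adjusted p = 0.0013, adjusted p = 0.578 with an estimated correlation) had 0 of 16 either way. In all, limma called 7 genes up and 43 down, with 1388 at an unadjusted p under 0.05, and an interaction of medium with log2 time called 17. Without the 3, 6, 12 or 48 h pair the count was 0 (1234, 1142, 1438 and 823 at an unadjusted p under 0.05), without 72 h it was 3 and without 24 h 242. The immediate early list missed the threshold without 3 h (adjusted p = 0.272) or 48 h (0.169), hypoxia without 48 h (0.104), and histones without 3 h (0.0582), 12 h (0.324) or 24 h (0.148).

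Change with time in culture was tested as a slope over both media. The control and CAF medium libraries of a time were counted as separate replicates, so scatter shared by a time can make these p-values too small. The first principal component held 57% of the variance of the mRNA libraries, with controls at -32.1, -37.4, -28.9, -23.9, 10.8 and 30.8 from 3 to 72 h and CAF medium libraries at -17.6, -8.24, -4.64, 16.6, 48.7 and 45.9, above the control at each time. With medium as a term, TXNIP rose by log2 1.07 ± 0.12 per unit of log2 time (adjusted p = 0.000232), CALY by 0.72, TNNI3 by 0.69, PIP by 0.68 and PTGS2, the inducible cyclooxygenase gene, by 0.67. EPCAM rose by 0.54 (adjusted p = 0.000232), CDH1 by 0.38 (adjusted p = 0.00547), IL8 by 0.57 (adjusted p = 0.00225) and FN1 by 0.33 (adjusted p = 0.00328), while CDH2 fell by 0.19 (adjusted p = 0.000986). RNU6-66P (-0.74), MYBL2 (-0.63), RRM2 (-0.61), MIR548AI (-0.58) and FAM111B (-0.56) had the largest falls. RNU6-66P and MIR548AI are short models with near-identical copies.

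The mitosis list (20 of 20 down both over all genes and adjusted over the list alone, adjusted p = 3.48e-11) and DNA replication (17 of 20 both ways, adjusted p = 2.24e-11) fell with time, each with adjusted p = 0.606 with an estimated correlation. So did the histone (6 of 11 both ways, adjusted p = 0.00292), hypoxia (1 up and 7 down of 19, 1 and 8 adjusted over the list alone, adjusted p = 0.0031) and NRF2 lists (4 of 17 both ways, adjusted p = 0.0143), again with adjusted p = 0.606 with an estimated correlation. The sterol (13 of 18 both ways, adjusted p = 0.000255) and STAT3 lists (8 of 15 both ways, adjusted p = 0.011) rose, with adjusted p = 0.606 with an estimated correlation, as did NF-kB (9 of 18, 10 adjusted over the list alone, adjusted p = 0.00637, adjusted p = 0.626 with an estimated correlation). NRF2 missed the threshold without the 3 h pair (adjusted p = 0.138). In all 2532 genes rose and 1603 fell by limma, a split of 2035 and 2238 under median centring and of 2006 and 2108 under quantile normalization. The count was 2668 without the 6 h pair, 2649 without 48 h and 1572 without 72 h. Of the 729 genes up in CAF medium 627 also rose with time and 0 fell, and of the 497 down 349 fell and 3 rose. Early and late libraries differ in depth, and with a term for the 24 to 72 h libraries, added after the data were seen, limma called 0 genes (2825 at an unadjusted p under 0.05). Fitted within 24 to 72 h alone, 94.8% of the called genes kept the sign of their slope, and within 3 to 12 h 67.8%. They were called on these same libraries, so such shares are partly built in.

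**Figure D4:**
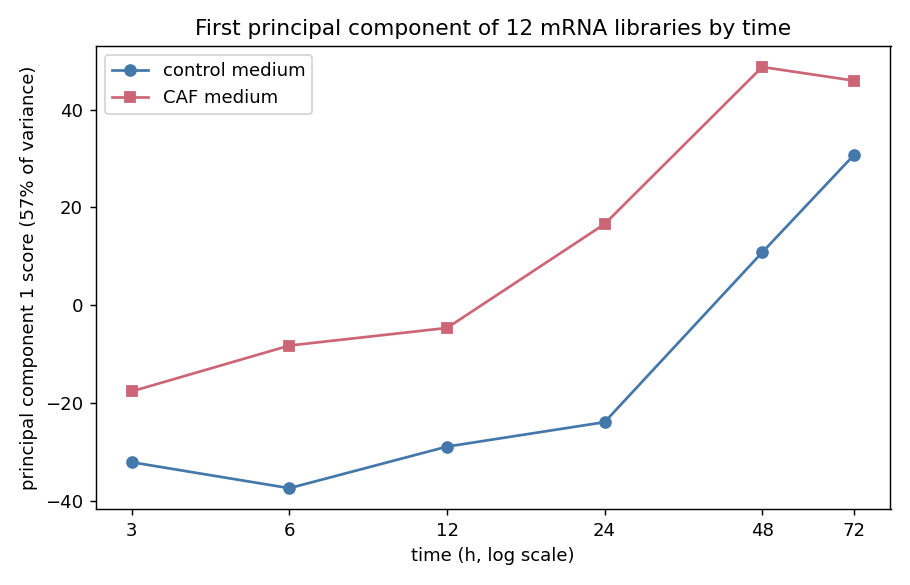
Position of each mRNA library on the first principal component (57% of the variance) against hours in culture. CAF medium libraries lie above the control at each of the 6 times, at 16.6 against -23.9 at 24 h.

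At single times, with 1 library per medium, values are descriptions of these libraries. At 3 h KRT19 measured 1.94 RPKM in control and 16.6 in CAF medium, and ANKRD1, a target of YAP signalling, 114.9 and 13.4. At 6 h HES7 measured 0.5 and 7.62 and BC005927 68.4 and 19.0, and at 12 h LINC00263 3.58 and 22.4 and DQ584698 24.3 and 1.93. CCL2 measured 20.7 and 5.21 at 6 h and 23.3 and 6.73 at 12 h. TXNIP measured 0.08 and 2.12 at 3 h, 0.11 and 2.94 at 6 h, 0.32 and 3.7 at 12 h, 0.64 and 11.8 at 24 h and 6.81 and 56.1 at 48 h. At 24 h MIR21 measured 0.75 and 10.2, DQ597485 590.3 and 83.3 and RRM2 70.4 and 16.7. At 48 h GDF15 measured 18.04 and 129.4, TFRC 36.4 and 4.84 and SAMD15 5.4 and 0.42. At 72 h DQ597485 measured 143.7 and 515.4, MIR5095 5.06 and 18.6, MCM10 3.05 and 0.62 and MYBL2 12.9 and 3.77.

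The numbers of genes at least 2-fold higher and lower on the log2(RPKM + 0.5) scale were 144 and 118 at 3 h, 279 and 117 at 6 h, 356 and 160 at 12 h, 407 and 85 at 24 h, 269 and 381 at 48 h and 18 and 91 at 72 h. The medium effects of 2 times, each with its own control, correlated across genes with a mean Pearson r of 0.352, from -0.0542 to 0.644, where genes are not independent replicates.

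For the small RNAs the question was which miRNAs CAF medium changed. None of the 470 tested passed over the 6 times (limma, 0 past the threshold, 49 at an unadjusted p under 0.05; edgeR on recovered reads, 0 and 48). The smallest p-values belonged to miR-34c-5p, a miRNA induced by p53, at 280.9 ± 122.0 RPM (miRNA reads scaled to the same total in each library) in control and 569.6 ± 404.9 in CAF medium (log2 0.87 ± 0.18, adjusted p = 0.118), miR-4654 (18.6 and 40.5, log2 1.06 ± 0.20, adjusted p = 0.118) and miR-145-5p (12.5 and 24.6, log2 0.96 ± 0.20, adjusted p = 0.118). Next among the miRNAs that were higher came miR-146a-5p, a feedback inhibitor of NF-kB signalling (788.8 and 1241, log2 0.64 ± 0.16, adjusted p = 0.154), and the predicted miRNA chr12_5497 (log2 1.49, adjusted p = 0.191), each higher at 6 of 6 times. Lower were chrX_42916 (log2 -1.73, adjusted p = 0.118), chr11_2945 (-1.06, adjusted p = 0.118), miR-33b-3p (-1.07, adjusted p = 0.121) and chr1_17673 (-0.75, adjusted p = 0.151) at 6 of 6 times and miR-3613-3p (-1.11, adjusted p = 0.172) at 5 of 6.

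**Figure D5:**
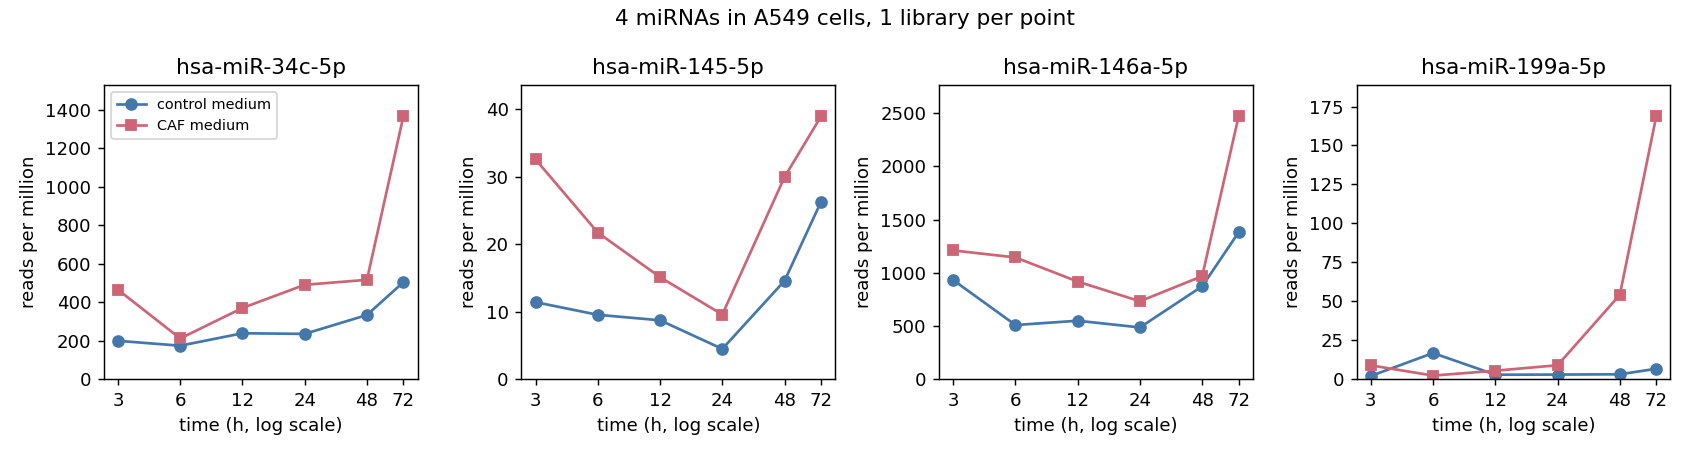
RPM of selected miRNAs against hours in culture, with 1 point per library in control and in CAF medium. miR-34c-5p lies higher in CAF medium at 6 of 6 times, and miR-199a-5p reaches 54.2 and 168.6 in CAF medium at 48 and 72 h.

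Over 3 to 12 h, 24 to 72 h and in their difference limma also called 0 miRNAs (41, 32 and 17 at an unadjusted p under 0.05, smallest adjusted p = 0.364, 0.46 and 0.903), and edgeR 0 (42, 23 and 16). The values with the smallest p over 3 to 12 h were those of miR-145-5p (log2 1.09), miR-4654 (1.11), miR-1246 (1.64) and miR-4454 (1.25) upward and chr11_2945 (-1.39), miR-3613-3p (-1.60), chr1_17673 (-1.02) and miR-548c-3p (-1.61) downward. Over 24 to 72 h they were miR-34c-5p (1.04), miR-199a-5p (3.17 ± 0.86), miR-3182 (1.08) and miR-4654 (1.01), and miR-2115-3p (-0.94), miR-33b-3p (-1.33), chrX_42916 (-2.02) and chr1_15900 (-0.97). In the difference they were miR-3182 (1.31), miR-126-5p (0.81), miR-425-3p (1.67) and chr9_40538 (1.76), and miR-3529-3p (-1.26), chr1_15900 (-1.02), miR-7-5p (-1.10) and miR-4454 (-1.30). The tests had limited power here: of simulated miRNAs changed by log2 1 the tests found 69.2% over the 6 times, 53.8% over 3 to 12 h, 23.1% over 24 to 72 h and 0% in the difference. Each share rests on 13 simulated miRNAs. That is too few to rank the early against the late fit, which have 3 pairs each.

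With time in culture 37 miRNAs rose and 39 fell by limma (edgeR 37 and 43), a split of 57 and 22 when values were rescaled without the 3 most abundant miRNAs. miR-216b-5p rose by log2 0.85 per unit of log2 time (adjusted p = 0.00734), miR-6503-5p by 0.74, miR-4663 by 0.70 and miR-3607-3p by 0.70, and miR-501-3p fell by 0.47 (adjusted p = 0.0032), miR-545-3p by 0.51 and miR-625-5p by 0.46. The predicted chr12_5116, a run of a single base and so of doubtful origin, fell by 0.83 (adjusted p = 0.0235). The count was 21 without the 3 h pair, 36 without 6 h and 46 without 48 h, and 0 in the controls alone (limma, 70 at an unadjusted p under 0.05).

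In the miRNA families, also set before the data were examined, no member passed over all miRNAs for the medium effect (limma, 0, with 49 of all 470 at an unadjusted p under 0.05; edgeR 0 and 48). Adjusted over the list alone, 1 of 2 in miR-34 and miR-449, 2 of 8 fibroblast-rich miRNAs and 1 of 8 inflammation miRNAs were higher over the 6 times, and 0 in the other 12 families. Over 3 to 12 h these counts were 1 in miR-34 and miR-449 and 1 fibroblast-rich miRNA, over 24 to 72 h 1 in miR-34 and miR-449, and in the difference 0. With time, 1 miRNA of miR-34 and miR-449 rose over all miRNAs and adjusted over the list alone, while 1 of let-7, 2 of miR-17-92, 1 of miR-23, miR-24 and miR-27, 1 fibroblast-rich, 1 blood and liver and 1 inflammation miRNA fell. Adjusted over the list alone the numbers of falls were the same except for 2 in miR-23, miR-24 and miR-27 and 1 in miR-221 and miR-222. The miR-29, miR-30, miR-15 and miR-16, miR-181, miR-10, miR-200 and hypoxia families had 0 either way. The miR-200 family, known to repress ZEB1 and ZEB2, was scarce: miR-141-3p averaged 54.9 and miR-200c-3p 24.8 RPM, and the other 7 of its 9 arms from 0.0975 to 8.30. miR-21-5p averaged 28.8% of the reads, miR-27b-3p 6.78% and miR-27a-3p 3.17%, and the predicted chr12_5220 and chr18_13667 averaged 23.1% and 8.67%. Close family members differ by few bases, and their reads may be divided between them.

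At 3 h miR-19a-3p measured 372.8 RPM in control and 1882 in CAF medium, and miR-19b-3p 1726 and 7364. The values at 48 h were 300.6 and 967.8 for miR-19a-3p and 1086 and 3770 for miR-19b-3p. Both were also higher in CAF medium at 12 h. They were lower at 6 h (615.1 and 262.4, 2589 and 1190) and at 24 h (888.8 and 650.1, 3603 and 2817). At 72 h miR-19a-3p was lower (1356 and 1183) and miR-19b-3p slightly higher (5065 and 5206). Lower in CAF medium at 3 h were chr1_16123 (3826 and 245.2) and chr16_10582 (445.0 and 41.1), and at 6 h miR-515-5p (129.0 and 22.8) and chr1_17590 (217.9 and 40.3). The predicted chr12_5497 was the largest or next largest rise at 6, 12 and 24 h (286.1 and 1432, 468.9 and 2243, 558.0 and 4970), beside chr8_39638 at 6 h (15.3 and 139.2), chr8_37611 at 12 h (38.2 and 96.5) and miR-216b-5p at 24 h (34.4 and 122.1). Falls at the later times were those of chrX_42916 at 12, 24, 48 and 72 h (204.4 and 70.1, 134.9 and 71.8, 65.3 and 3.46, 35.4 and 14.2), chr1_16123 at 12 h (824.4 and 309.7), chr3_24262 at 24 h (203.3 and 110.8) and chr1_17590 at 72 h (72.7 and 25.9). miR-7158-5p measured 410.2 and 28.8 at 48 h and 4.28 and 40.1 at 72 h, and chr2_21899 33.6 and 263.0 at 72 h.

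The numbers of miRNAs at least 2-fold higher and lower were 47 and 57 at 3 h, 39 and 88 at 6 h, 14 and 18 at 12 h, 32 and 12 at 24 h, 48 and 49 at 48 h and 37 and 22 at 72 h. The median change over all miRNAs was log2 -0.28 at 6 h as deposited, and median centring moved it by 0.49. The effects of 2 times correlated with a mean r of 0.127, from -0.322 between 3 and 6 h to 0.447. With the 3 and 6 h pairs left out together, an alternative added after the data were seen, the mean r was 0.171 and limma still called 0 miRNAs (71 at an unadjusted p under 0.05).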

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

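The comparisons with other assignments of the libraries were planned, and the tests of technical explanations in this part were chosen only after the results were seen. Exchanging the media within times gives 32 assignments. The real one called 1226 genes and the others at most 0 (1 of 32 as large). That share is under 0.05 but is the smallest that 32 assignments can give. It argues against chance for that count without excluding it, and the exchange treats the 6 times as independent. For change with time 1 of 100 drawn orders of the times, the real one, gave as many genes (4135 real, 3985 highest other). For miRNAs 2 of 100 did (76 real, 92 highest other). Both shares are under 0.05, but another order came close for genes and called more miRNAs. The comparison asks only about the order of 6 times. It cannot tell a steady trend from a step between the 3 to 12 h and 24 to 72 h libraries. For the 11 gene lists called over the 6 times chance cannot be excluded, since 3 of 32 assignments gave as many and the highest other gave 12. The early and late counts (677 and 492 genes, highest other 0 and 0) have only 4 assignments and the difference (50 genes, highest other 0) only 10 splits, too few for a share under 0.05. For miRNAs over the 6 times the real count was 0 (highest other 0), so that each of 32 assignments gives as many by construction and the comparison says nothing about chance. The miRNA counts over 3 to 12 h and 24 to 72 h (0 real, highest other 0, as many in 4 of 4 each) and in the difference (0 real, highest other 0, as many in 10 of 10) had too few assignments for a share under 0.05.

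Late and early effects differed by a direct test in 50 genes, which singles out IL6 (log2 2.35), PIP (2.12), STC2 (1.50), SOD2 (1.50) and BC016015 (1.28) upward and MYBL2 (-1.75), C2orf48 (-1.75), CDC25C (-1.72), SPC25 (-1.60) and KIF20A (-1.53) downward. The list medians that differed were those of NF-kB (1.14), immediate early genes (0.355), hypoxia (0.307), STAT3 (0.258), histones (-0.392), DNA replication (-0.730) and mitosis (-1.13), none of which passed when the correlation between genes was estimated (adjusted p from 0.0984 to 0.578). These calls for single genes end without the 3, 6, 12 or 48 h pair (0 genes by limma, 1234, 1142, 1438 and 823 at an unadjusted p under 0.05).

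The NF-kB and cytokine list was low in CAF medium at 3, 6 and 12 h. A raised control at 3 h as the whole cause is argued against by the medians at the other early times, of which the higher was -0.707. It may still add to the effect at 3 h, where the control's list median was 0.484 after centring each gene on its mean. The controls of 6, 12, 24 and 48 h stood at -0.173, -0.025, -0.104 and 0.252, and that of 72 h at 0.608. Scaling is argued against by an early median of -0.99 under the alternative that brought it nearest to 0, and members near the detection limit by a median of -0.97 over those with a mean of at least 5 RPKM. Cultures running ahead in time are argued against for this list, since its highest early median in CAF medium minus the lowest control median of any time, that of 6 h, was -0.525 and 18 of 18 members were below that control on average. What stays open, and was not tested, is a difference in composition between conditioned and control medium other than the factors of CAF cells, such as serum or nutrients, beside a response to those factors.

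The medium effect ran along the change with time: across 12029 genes the effect over the 6 times and the slope correlated with r = 0.749. Without the mitosis and DNA replication lists r was 0.745, but 11989 genes remained. So few genes were taken out that this value cannot tell whether genes of cell division carry the correlation. A bias of gene length or level as the whole cause is argued against by a median partial correlation of 0.455 between each time's effect and the trend of the other controls, from 0.76 at 24 h (0.755 without the adjustment) to only 0.136 at 72 h (0.126), and by correlations of the effect with length of either sign (0.198 at 3 h, -0.172 at 12 h). A swap of the 24 h CAF medium and 48 h control libraries stays open. They are the closest mRNA pair (r = 0.9931, against 0.9697 for the former with its own control). Each is less close to any library of its own medium (at most 0.981 and 0.9852). ID2 and ID3 lay as the sample names say (8.10 and 28.2 RPKM in the 24 h CAF medium library, 23.7 and 51.5 in the 48 h control). These genes, however, were called lower in CAF medium in fits that held both libraries under these names. Their position is thus partly built in and decides nothing. Of 33 genes whose media separate at 3, 6, 12 and 72 h against the control trend, 21 (63.6%) also lay as the names say. That share ran from 38.5 to 84.8% for 4 other such pairs of times and so decides nothing either. The genes of those 4 pairs were chosen at times that include 24 h, 48 h or both. Their choice thus used at least 1 of the libraries in question, which limits them as a yardstick. With both libraries left out, effect and control trend correlated at 0.389, 0.5659 and 0.4092 at 3, 6 and 12 h and at -0.1117 at 72 h. That cultures in CAF medium run ahead in time also stays open as a hypothesis: 5 of 5 CAF medium libraries of 3 to 48 h were closest to a later control (at 12 h by 0.9659 against 0.9656), which largely restates the pattern, and of 6 lists called both over the 6 times and with time 5 moved the same way while NF-kB moved the opposite way, as did the BMP and ID members (5 of 6 positive with time, 0 of 6 in CAF medium).

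miR-199a-5p, made by fibroblasts and scarce in many epithelial cells, stood at 54.2 RPM in CAF medium against 3.17 in control at 48 h (47 against 5 reads) and at 168.6 against 6.72 at 72 h (286 against 11 reads), but at 6 h it was lower in CAF medium (2.35 against 16.8). Counting noise is argued against by ratios of 17.1 and 25.1, with lower exact 95% bounds of 6.82 and 13.8. Fibroblast cells carried over could not be tested to an end: COL1A2, COL3A1, POSTN, LUM and DCN had a median difference of at most 0.04 RPKM at 48 and 72 h, but the share needed is unknown and nothing says that both assays used the same RNA. Nor could transcription of its host gene, since DNM3OS was at most at 0.01 RPKM in the CAF medium libraries of 48 and 72 h and a host transcript can be processed before it is counted. miRNA taken up from the medium may be a further source and was not tested.

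Some libraries stood apart within their group of 6, by a gap to the nearest library that took the given share of the whole range. This was so in 15 of 124 groups. Chance gives about 5% for repeated samples, but a group here holds 6 different times, so a steep change with time, as for TXNIP and CALY, can set the last time apart by itself. In control medium at 72 h they were TXNIP (0.688 of the range, 21.7 against 6.81 RPKM), FXYD7 (0.785, 2.41 against 0.55), CALY (0.779, 3.53 against 0.78) and BC015429 (0.726, 16.8 against 5.73). CCL2 in control medium at 3 h (0.813, 85.3 against 25.2 RPKM), TWIST1 in control medium at 48 h (0.643, 14.6 against 9.33) and VIM in CAF medium at 72 h (0.79, 220.7 against 461.2) were the others among genes. The CAF medium library of 12 h stood apart on the second principal component (0.63, -40.5 against -10.9), and the control small RNA library of 6 h in depth (0.639, 5.77 against 3.09 M reads). In CAF medium miR-27a-3p (0.66, 47220 against 33300 RPM) and miR-141-3p (0.796, 138.7 against 44.2) stood apart at 3 h. At 72 h miR-34c-5p (0.736, 1364 against 516.1), miR-146a-5p (0.725, 2470 against 1211) and miR-199a-5p (0.688, 168.6 against 54.2) did so, and miR-199a-5p also in control medium at 6 h (0.687, 16.8 against 6.72).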

How the results depend on the processing

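The fits without the 3 h and 6 h small RNA pairs and with a term for the 24 to 72 h libraries were chosen after the data were seen, and the other alternatives before. Of the single-gene values under alternatives, 366 kept direction and side of the threshold, 75 lost a call, 4 gained one and 11 changed sign, and of the miRNA values 212 were kept and 6 changed sign. Without a filter on low values limma called 0 genes over the 6 times, 0 over 3 to 12 h, 36 over 24 to 72 h and 0 in the difference (4744, 3797, 3496 and 1968 at an unadjusted p under 0.05), where more and lower genes were tested. With a mean of at least 5 RPKM the counts were 601 over the 6 times, 365 over 3 to 12 h and 2558 for change with time, where fewer were tested. Without a time term the overall count was 0 (1691 unadjusted), with adjusted p from 0.331 to 0.427 for the named genes that had passed. The difference had 0 calls without the mean-variance trend (1369 unadjusted) and 17 as an interaction with log2 time. Change with time had 2443 genes and 0 miRNAs (70 unadjusted) in the controls alone, and 0 genes and 0 miRNAs (2825 and 33 unadjusted) with a term for the 24 to 72 h libraries, and 26 miRNAs with a mean of at least 100 RPM.

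Leaving out each time gave 34 to 1399 genes over the 6 times, 0 to 1084 over 3 to 12 h, 31 to 542 over 24 to 72 h, 0 to 242 in the difference, 1572 to 4296 with time, and 21 to 82 miRNAs with time. Gene lists called ranged from 10 to 11 over the 6 times, 4 to 7 early, 8 to 12 late, 6 to 10 in the difference and 8 to 11 with time. With an estimated correlation camera called 0 lists in each fit, and fry called 1 list over the 6 times, 1 early, 3 late, 0 in the difference and 6 with time. The count of gene and time combinations at least 2-fold apart (2425) was 86 at 4-fold, 3687 and 1553 with pseudocounts of 0.1 and 1, and 1146 with a mean of at least 5 RPKM. For miRNAs (463) it was 72 at 4-fold, 237 with a pseudocount of 10, 3075 without a filter, 104 with a mean of at least 100 and 973 when rescaled without the 3 most abundant. SNAI2 and ACTA2 lost their calls with a log2 time term (adjusted p = 0.066 and 0.0738), and MMP2 gained one by median centring (0.0491).

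VIM changed sign by median centring (-0.01064) and quantile normalization (-0.04696), and ranged from -0.04097 to 0.09852 over the left-out times. FN1 ranged from -0.009359 to 0.2654, ZEB2 from -0.09635 to 0.009318, IL6 from -0.6777 to 0.02889, IL8 from -0.3999 to 0.202 and miR-200c-3p from -0.1582 to 0.1053, with 0.04473 by median centring and 0.00449 by quantile normalization. Apart from the filters, the cause was not tested. Depth limits the small RNA values: 0.868 M reads make 10 RPM fewer than 10 reads in that library.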

Other observations

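All tests in this part were chosen after the data were seen; the values come without an explanation. Among the predicted miRNAs, chr12_5220 and chr18_13667, which averaged 23.1% and 8.67% of the reads, share a run of 11 bases, as does chr1_14689 (848.6 RPM) with the first. All 3 have 18 bases, the shortest length in the table. chr7_35153 and chr7_36447 are each other's reverse complement and hold the same mean of 489.0 RPM. Which RNA these sequences come from was not analysed here, and any RPM value depends on whether they are counted as miRNAs. The share of chr12_5220 ranged from 14.2 to 37.6%.

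The expression of fibroblast genes in these libraries gives the background for any RNA from CAF cells. COL1A2, COL3A1 and POSTN stayed at or below 0.12, 0.16 and 0.11 RPKM in each of the 12 mRNA libraries, and LUM and DCN at or below 1.43 and 0.6. FAP and FBN1 reached 4.71 and 5.36 RPKM in CAF medium at 48 h, with 4.09 and 4.67 in control. At 72 h both were lower in CAF medium (2.06 and 3.57 RPKM) than in control (2.46 and 4.23). COL1A1 was higher in CAF medium at 3, 6, 12 and 24 h (5.81, 4.02, 4.84 and 4.31 RPKM against 1.91, 1.37, 2.89 and 2.45) and lower at 48 and 72 h (3.65 and 2.60 against 4.18 and 4.27). THY1 was higher at 6 of 6 times, with 1.27 against 0.17 RPKM at 24 h and 2.22 against 1.18 at 72 h.

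Among the small RNA libraries of 3 and 6 h the closest pairs cross both medium and time. The CAF medium library of 3 h and the control of 6 h correlated at 0.9741 and the control of 3 h and the CAF medium library of 6 h at 0.9666, against 0.9575 and 0.953 for the media of the same time and 0.9532 and 0.9586 within control and CAF medium. miR-10a-5p measured 6662 RPM in control and 3084 in CAF medium at 3 h and 1850 and 5498 at 6 h, and miR-18a-5p 113.3 and 355.2 at 3 h and 236.5 and 114.6 at 6 h. These 2 miRNAs were chosen after their values were seen. Others kept 1 direction: miR-34c-5p measured 199.5 and 464.8 at 3 h and 174.1 and 211.6 at 6 h, and miR-146a-5p 931.9 and 1211 at 3 h and 509.6 and 1145 at 6 h. Those, however, were named for a small p under the same sample names. An exchange of sample names among these 4 libraries stays open.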
